A study of Mus musculus with 26 samples.

How the data were processed

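RNA from mouse J1 embryonic stem cells was hybridised to Affymetrix Mouse Gene 2.0 ST arrays. Per the labels' protocols, the cells grew in serum with leukaemia inhibitory factor above a layer of irradiated fibroblasts from mouse embryos. Poly(A) RNA was purified from total RNA and labelled with biotin, per the labels' protocols. The labels describe the knockdown both as lentiviral short hairpin RNA and as transfected small interfering RNA, and do not say which arrays had which. They also do not say what the cells were incubated with for 4 h or 8 h. The deposited values are log2 signal intensities per probe set, made with RMA in the oligo package per the submitters' processing notes, which give no version. RMA corrects the background, makes the probe distributions of the arrays equal and summarises the probes of a probe set. Whether all 26 arrays were processed together is not stated.

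The 26 arrays fall into 13 groups of 2 by the labels. A time course holds 18 arrays in 9 groups: scramble control, Mettl14 knockdown and Mettl3 knockdown, each at 0 h, 4 h and 8 h. A repeat set at 0 h holds 8 arrays in 4 groups: each knockdown with a scramble control of its own. In that set, replicate 2 of each scramble control carries a description of 4 h, while its title, source and time field say 0 h, and it was grouped as 0 h. The arrays held 41345 probe sets. A probe table paired 23521 of them with exactly 1 gene symbol and 1814 with several symbols, and did not list 16010. Only the first kind was used for genes, which gave 22180 genes. For the 1082 genes with several probe sets, the probe set with the highest mean signal stood for the gene. The 7393 genes with the lowest mean signal, a fraction of 0.333, were left out, and 14787 were tested. Their lowest mean was 6 on the log2 scale. The only probe set listed with Mettl3 is also listed with Tox4, so its values are given for the pair. Probes of near-identical copies, such as those of the Zscan4 family, the histones and the ribosomal proteins, can bind the RNA of more than 1 copy, and changes of single members are uncertain for that reason.

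Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, two-sided), with Benjamini-Hochberg adjustment over the 14787 genes and a threshold of 0.05. The 18 arrays of the time course shared a single estimate of the spread with 9 residual degrees of freedom, and the 8 arrays of the repeat set another with 4. The comparisons were each knockdown against scramble at 0 h in each set, 8 h against 0 h in each treatment, and the difference between the 8 h change in a knockdown and that in scramble. The 4 h changes, the knockdowns against scramble at 4 h and 8 h, and the difference between the knockdown effects of the sets were computed beside them. The last came from a fit over all 26 arrays. Apart from values over a gene list, ± gives the standard error from limma of a log2 change between groups of 2 arrays. For a mean or median over list members, or a difference of such values, it comes from the standard error of the mean over the members. That error treats genes as independent and does not measure the spread between arrays. The p-values measure the spread between these samples, which the labels do not place in separate experiments.

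Changes of 20 fixed gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, and again with the correlation estimated. The p-values were adjusted over the 180 tests of 20 lists in 9 comparisons. With the preset correlation 70 tests passed and with the estimated correlation 33 of those passed. The lists were core and naive pluripotency, primed epiblast, neuroectoderm, mesoderm, endoderm, trophectoderm, Hox clusters, feeder fibroblast markers, m6A writers with erasers and readers, the insulin-like growth factor system, interferon response, p53 targets, short-lived transcripts, long-lived metabolic and cytoskeletal transcripts, ribosomal proteins, cell cycle, amino acid and unfolded protein stress, FGF-ERK feedback, two-cell-like genes and replication-dependent histones. The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where the text says otherwise. By that rule, each comparison names the 6 largest rises and the 6 largest falls that passed, leaving out unnamed and predicted genes, and up to 4 members of each list with the smallest adjusted p. Mettl3, Mettl14, Pou5f1, Nanog, Sox2, Klf4, Esrrb, Myc, Igfbp3, Cdkn1a, Actb and Gapdh belong to it in every comparison. A gene named in a comparison may be given its value in another.

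Alternatives covered the filter on dim genes, the mean of a gene's probe sets, an eBayes fit with trend and robust, array weights, replicate blocks, quantile normalization again within a set, an equal median of the long-lived list in every array, a fit over all 26 arrays, the 6 arrays of the time course at 0 h alone, and leaving out each array in turn. With an array left out its partner stands alone, and is assumed to vary like the arrays of the other groups. The method was tested on simulated data built on the arrays, with 50 genes changed at each fold over 14787 genes. For Mettl14 knockdown in the time course it called 48% of genes changed 1.25-fold, 86% of those changed 1.5-fold and 98% of those changed 2-fold, with 9 unchanged genes called. For the Mettl14 difference of 8 h changes it called 10%, 62% and 92% of them, with 7 unchanged genes called. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.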

Results

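Transcript levels in mouse J1 embryonic stem cells were measured on 26 arrays after knockdown of Mettl3 or Mettl14. Their products form the enzyme complex that places N6-methyladenosine (m6A) on messenger RNA, and the series asks how this mark relates to the stability of transcripts of developmental regulators. The time course had 9 groups of 2 arrays, and the repeat set at 0 h had 4 groups of 2 arrays. Values ran from 0.754 to 14.32 on the log2 scale, and replicates correlated across probe sets at r = 0.9869 to 0.9926. The number of arrays per group, 2, limits the precision.

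The targeted transcripts were lower in each knockdown. Mettl14 had a mean log2 signal of 9.09 in scramble and 7.40 in its knockdown at 0 h of the time course, a change of -1.70 ± 0.13 to 30.9% of the control (adjusted p = 9.59e-07). In the repeat set Mettl14 changed by -1.36 ± 0.10 to 39% of its control (adjusted p = 0.000158). For Mettl3, the probe set 17306289 shared with Tox4 changed by -1.89 ± 0.10 in the Mettl3 knockdown of the time course, to 26.9% of the control, and by -2.08 ± 0.06 in the repeat set, to 23.6%. A probe set listed with Tox4 alone did not pass in those comparisons, at 0.10 ± 0.06 and -0.17 ± 0.07. The shared probe set was also lower after Mettl14 knockdown, at -0.50 ± 0.10 and -0.45 ± 0.06 (adjusted p = 0.00162 and 0.00184), whereas Mettl14 did not pass after Mettl3 knockdown, at -0.10 and -0.22. At 8 h Mettl14 stood at 15.9% of scramble in its knockdown, and the probe set shared by Mettl3 and Tox4 at 16% in the Mettl3 knockdown.

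Knockdown of Mettl14 at 0 h of the time course lowered 24 of 34 pluripotency genes and raised keratins such as Krt8. The cells' self-renewal regulators fell: Tcl1 (-1.54 ± 0.06), Klf4 (-1.20 ± 0.10), Esrrb (-1.09 ± 0.08), Nanog (-0.72 ± 0.05) and Pou5f1 (-0.74 ± 0.11), while Sox2 did not pass at -0.25 ± 0.10 (adjusted p = 0.055). Keratins of simple epithelium rose, with Krt8 at 2.34 ± 0.05, Krt18 at 2.24 ± 0.05 and Krt19 at 2.08 ± 0.08. The largest rises were Cysltr1, a leukotriene receptor, at 3.54 ± 0.17, Thbs1, a matrix glycoprotein, at 3.48 ± 0.09 (adjusted p = 1.56e-10), H2-M2 at 3.22 ± 0.09, Sema6a at 3.19 ± 0.09, Fgf5, a marker of the primed epiblast, at 3.02 ± 0.12, and Nefl at 2.92 ± 0.08. The largest falls were in Zscan4e at -2.94 ± 0.18, Zscan4b at -2.78 ± 0.25 and Zscan4c at -2.55 ± 0.24, members of a family switched on in cells resembling the two-cell embryo, in Srgn at -2.52 ± 0.27, the cell adhesion gene Ceacam1 at -2.44 ± 0.09 and Pramel19 at -2.20 ± 0.25. The reference genes Actb and Gapdh did not pass, at 0.15 ± 0.08 and 0.03 ± 0.04. In all, 2868 genes rose and 2978 fell of 14787, of which 335 and 123 changed at least 2-fold. Setting the long-lived list equal moved this split to 2174 and 3503.

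By gene list, 24 of 34 pluripotency genes fell after Mettl14 knockdown, and 26 adjusted over the list alone (list test adjusted p = 1.82e-11), with Tfcp2l1 at -1.09 ± 0.06 and Fbxo15 at -1.08 ± 0.06 among them. Primed epiblast genes rose in 8 of 13 cases, also 8 adjusted over the list alone (adjusted p = 0.000826), including Lef1 at 1.40 ± 0.12 and Pou3f1 at 1.19 ± 0.09. Of 22 targets of p53, the stress-activated transcription factor, 17 rose, also 17 adjusted over the list alone (adjusted p = 1.67e-09). They included Plk2 at 1.91 ± 0.10, Perp at 1.39 ± 0.09 and the cell cycle inhibitor Cdkn1a at 1.32 ± 0.11. The insulin-like growth factor system rose in 8 of 13 genes, also 8 adjusted over the list alone (adjusted p = 2.53e-05). Its members included Irs2 at 2.01 ± 0.12, Igfbp3 at 1.95 ± 0.08 and Irs1 at 1.31 ± 0.13. Short-lived transcripts, mostly early response genes, rose in 23 of 40 cases and fell in 5, with 24 higher adjusted over the list alone, and Ccn1 at 2.43 ± 0.09 and Jun at 1.49 ± 0.09. That list passed at adjusted p = 3.76e-05, but at adjusted p = 0.0757 with an estimated correlation. Trophectoderm genes rose in 9 of 19 cases, and in 10 adjusted over the list alone (adjusted p = 0.0165, and adjusted p = 0.0716 with an estimated correlation), the keratins included. Markers of feeder fibroblasts rose in 11 of 23 cases, and in 13 adjusted over the list alone (adjusted p = 5.2e-05). Among them were Tagln at 2.22 ± 0.07, Mmp2 at 1.48 ± 0.08 and Fstl1 at 1.41 ± 0.05, while the median of its 8 measured collagens was 0.22.

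Cell cycle genes fell in 19 of 38 cases after Mettl14 knockdown, and in 24 adjusted over the list alone (adjusted p = 8.54e-06), with small changes such as -0.37 ± 0.05 for Mcm3 and -0.36 ± 0.05 for Top2a. The stress list of amino acid and unfolded protein responses fell in 12 of 25 genes, also 12 adjusted over the list alone, with Chac1 at -1.30 ± 0.11. The list test gave adjusted p = 0.0126, and adjusted p = 0.0757 with an estimated correlation. Two-cell-like genes fell in 6 of 10 cases, also 6 adjusted over the list alone. This list passed at adjusted p = 0.00208, and adjusted p = 0.107 with an estimated correlation. Lineage lists went both ways and did not pass: neuroectoderm (Nes 2.06 ± 0.07, Tubb3 -1.22 ± 0.08; adjusted p = 0.996), mesoderm (Eomes 1.00 ± 0.11, Bmp4 -1.68 ± 0.13; 0.946) and endoderm (Cubn -2.18 ± 0.11; 0.717). FGF-ERK feedback genes also went both ways, 6 up, such as Dusp4 at 1.35 ± 0.09, and 5 down of 16 (adjusted p = 0.554). The Hox list did not pass (adjusted p = 0.537). Of 37 long-lived transcripts 5 rose and 4 fell (adjusted p = 0.993), and of 59 ribosomal protein genes 2 rose and 5 fell (0.334). Interferon response genes fell in 4 of 14 cases (adjusted p = 0.431), and histones in 3 of 17 (0.0702, reaching 0.0343 and 0.0328 without replicate 1 or replicate 2 of Mettl14 knockdown at 8 h). Among the m6A writers, erasers and readers, 5 rose, such as the reader Igf2bp3 at 1.17 ± 0.05, and 5 fell of 18 (adjusted p = 0.715).

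Mettl3 knockdown at 0 h of the time course also lowered pluripotency genes, here 29 of 34, and raised the keratin gene Krt8. The regulators of self-renewal fell, Klf4 (-1.40 ± 0.10), Tcl1 (-1.31 ± 0.06), Esrrb (-1.09 ± 0.08), Stat3 (-0.95 ± 0.05), Nanog (-0.82 ± 0.05) and Tet1 (-0.71 ± 0.04). The epithelial keratin gene Krt8 rose by 2.51 ± 0.05 (adjusted p = 9.96e-12), and so did the neural progenitor gene Nes, by 2.28 ± 0.07. The largest rises were Thbs1 at 3.11 ± 0.09, Cysltr1 at 3.10 ± 0.17, Sema6a at 3.10 ± 0.09, Anxa3 at 2.87 ± 0.07, Fndc3c1 at 2.84 ± 0.05 and the smooth muscle gene Cnn1 at 2.77 ± 0.06. The largest falls were Zscan4e at -2.61 ± 0.18, Zscan4b at -2.44 ± 0.25, Ceacam1 at -2.34 ± 0.09, the endodermal receptor Cubn at -2.13 ± 0.11, Klk1 at -2.07 ± 0.29 and Zscan4c at -2.03 ± 0.24. In all, 2850 genes rose and 2744 fell, 323 and 120 of them at least 2-fold. Pluripotency genes fell in 29 of 34 cases, and in 31 adjusted over the list alone (adjusted p = 6e-15). The insulin-like growth factor system rose in 9 of 13 genes, also 9 adjusted over the list alone (adjusted p = 3.16e-05). The rises included Irs2 at 2.09 ± 0.12, Igfbp3 at 1.85 ± 0.08 and Igf1r at 0.82 ± 0.07. Targets of p53 rose in 14 of 22 cases, also 14 adjusted over the list alone (adjusted p = 2.16e-06). Plk2 lay at 1.47 ± 0.10, Cdkn1a at 1.35 ± 0.11 and Trp53inp1 at 0.87 ± 0.05. Feeder markers rose in 11 of 23 cases, also 11 adjusted over the list alone (adjusted p = 0.000117), with a collagen median of 0.23. Trophectoderm genes rose in 10 of 19, or 11 adjusted over the list alone (0.00165). Cell cycle genes fell in 19 of 38 cases, and in 20 adjusted over the list alone (adjusted p = 2.46e-05). Primed epiblast genes rose in 7 of 13 cases, or 8 adjusted over the list alone, Fgf5 at 2.45 ± 0.12 and Pou3f1 at 1.59 ± 0.09 among them. By camera it passed at adjusted p = 0.00219, and adjusted p = 0.0696 with an estimated correlation. Short-lived transcripts such as Ccn1 at 2.16 ± 0.09 and Jun at 1.59 ± 0.09 rose in 23 and fell in 5 of 40 cases, with 25 higher adjusted over the list alone. As a list they passed at adjusted p = 5.76e-05, and adjusted p = 0.0771 with an estimated correlation. The stress list fell in 13 of 25 genes and the two-cell-like list in 6 of 10, the same numbers adjusted over the list alone. The list test gave adjusted p = 0.0139 and 0.000495, and adjusted p = 0.0757 for each with an estimated correlation. The remaining lists did not pass, with adjusted p from 0.172 for histones to 0.742 for FGF-ERK feedback, though histones reached 0.0499 without replicate 2 of Mettl3 knockdown at 0 h. Sox2 passed at -0.30 ± 0.10 but lost its call without any of 3 arrays, with adjusted p = 0.0959 and 0.084 without replicate 1 or 2 of scramble at 0 h and 0.136 without replicate 1 of Mettl3 knockdown.

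Across the 14787 genes the knockdown effects of the time course at 0 h correlated at r = 0.907 (rho = 0.851), where genes are not independent replicates. Both used the same scramble arrays, and simulated unchanged groups sharing them gave r = 0.501. The covariance was 0.14 against 0.00562 in the simulation, a difference of 0.134. With 1 scramble array for each knockdown r was 0.846 or 0.847. Shared calls numbered 2236 higher genes and 2111 lower genes, where independent lists would share 552.8 and 552.6, and 36 genes were called in opposite directions.

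In the repeat set, Mettl14 knockdown lowered pluripotency genes and raised regulators of the trophoblast, the embryo's outer lineage. The genes that fell included Nr0b1 (-1.30 ± 0.05), Fgf4 (-1.19 ± 0.05), Tcl1 (-1.17 ± 0.05) and the DNA demethylase gene Tet2 (-1.12 ± 0.05). Esrrb (-0.67 ± 0.09), Pou5f1 (-0.46 ± 0.05), Klf4 (-0.44 ± 0.06) and Sox2 (-0.42 ± 0.05) fell too. Nanog passed at -0.22 ± 0.05 (adjusted p = 0.00963) but not without replicate 2 of Mettl14 knockdown, at -0.19 with adjusted p = 0.0558. Trophoblast regulators rose, with Tfap2a at 1.63 ± 0.09 and Cdx2 at 1.59 ± 0.08, together with Krt18 at 1.54 ± 0.05 and Krt8 at 1.36 ± 0.05. The largest rises were the kinase gene Nrk at 2.49 ± 0.10, Pmp22 at 2.24 ± 0.09, the cytokine gene Ltb at 2.07 ± 0.10, Tgfb2 at 1.90 ± 0.06, Wls, which is needed to secrete Wnt proteins, at 1.90 ± 0.08, and Parp8 at 1.89 ± 0.11. The largest falls were Ceacam1 at -2.43 ± 0.06 (adjusted p = 1.64e-05), the germline gene Morc1 at -2.16 ± 0.06, Pla2g1b at -2.02 ± 0.08, Lrrc2 at -1.68 ± 0.07, Spink1 at -1.56 ± 0.05 and Sohlh2 at -1.53 ± 0.09. In all, 2864 genes rose and 2494 fell, 149 and 80 of them at least 2-fold, and setting the long-lived list equal gave 3394 and 1855. By list, 30 of 34 pluripotency genes fell, or 31 adjusted over the list alone (adjusted p = 3.12e-13). Among trophectoderm genes 14 of 19 rose, also 14 adjusted over the list alone (2.17e-05). Short-lived transcripts rose in 24 of 40 cases and fell in 9, with 24 higher adjusted over the list alone (adjusted p = 3.67e-05), Ccn1 at 1.26 ± 0.05 and Egr1 at 0.94 ± 0.05 among them. The insulin-like growth factor system rose in 9 of 13 genes, also 9 adjusted over the list alone, Igf2 at 1.45 ± 0.05, Irs2 at 1.10 ± 0.06 and Igfbp3 at 0.62 ± 0.04. This list passed at adjusted p = 0.000561, and adjusted p = 0.0722 with an estimated correlation. Cell cycle genes fell in 14 of 38 cases, or 15 adjusted over the list alone. By camera it passed at adjusted p = 0.00104, and adjusted p = 0.221 with an estimated correlation. Two-cell-like genes fell in 6 of 10, also 6 adjusted over the list alone. As a list they passed at adjusted p = 0.00302, and adjusted p = 0.221 with an estimated correlation. The ribosomal protein list passed downward with 6 of 59 lower, at adjusted p = 0.0205, and adjusted p = 0.21 with an estimated correlation. It did not pass without replicate 1 of Mettl14 knockdown (0.066). Targets of p53 went both ways, 6 up and 6 down (adjusted p = 0.767), with Cdkn1a at 0.33 ± 0.05 and Ephx1 at -0.93 ± 0.10. Feeder markers rose in 9 of 23 cases, but the list did not pass (adjusted p = 0.0512) except without replicate 1 of the scramble control (0.024) or replicate 2 of the knockdown (0.0263). Primed epiblast genes rose in 5 of 13 cases, Fgf5 at 1.38 ± 0.08 among them, but the list did not pass (adjusted p = 0.55). The lists of neuroectoderm (0.424), mesoderm (0.299), endoderm (0.883) and stress (0.334) did not pass either.

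Mettl3 knockdown in the repeat set again lowered pluripotency genes, here Tcl1 (-1.07 ± 0.05), Tet2 (-1.05 ± 0.05) and Gbx2 (-1.03 ± 0.06), and raised the primed epiblast genes Fgf5 by 1.63 ± 0.08, Otx2 by 0.81 ± 0.05 and Dnmt3b by 0.67 ± 0.05. The largest rises were Pof1b at 2.10 ± 0.05, Ltb at 1.95 ± 0.10, Wls at 1.89 ± 0.08, the lipoprotein gene Apob at 1.88 ± 0.13, Casp8, which starts apoptosis, at 1.81 ± 0.09, and Fgf5. The largest falls were Morc1 at -2.49 ± 0.06, Ceacam1 at -2.23 ± 0.06 (adjusted p = 1.09e-05), Pla2g1b at -1.94 ± 0.08, Zscan4c at -1.85 ± 0.13, Zscan4b at -1.79 ± 0.07 and Zscan4e at -1.73 ± 0.05. In all, 2642 genes rose and 2571 fell, 110 and 81 of them at least 2-fold. Pluripotency genes fell in 28 of 34 cases, or 29 adjusted over the list alone (adjusted p = 3.4e-13). The insulin-like growth factor system rose in 11 of 13 genes, also 11 adjusted over the list alone (adjusted p = 3.67e-05). Igf2 lay at 1.16 ± 0.05, Irs2 at 1.13 ± 0.06 and Igfbp3 at 0.67 ± 0.04. Feeder markers rose in 10 of 23 cases, or 11 adjusted over the list alone (adjusted p = 9.95e-05). Short-lived transcripts rose in 22 and fell in 7 of 40, with 23 higher adjusted over the list alone (9.48e-05). Two-cell-like genes fell in 9 of 10 cases, also 9 adjusted over the list alone. The list test gave adjusted p = 3.28e-06, and adjusted p = 0.09 with an estimated correlation. Cell cycle genes fell in 16 of 38, also 16 adjusted over the list alone. This list passed at adjusted p = 0.000843, and adjusted p = 0.219 with an estimated correlation. Trophectoderm genes rose in 12 of 19 and primed epiblast genes in 7 of 13, the same numbers adjusted over the list alone. By camera it passed at adjusted p = 0.00185 and 0.00834, and adjusted p = 0.0757 and 0.107 with an estimated correlation. Targets of p53 passed downward, with 9 of 22 lower and 3 higher, or 10 lower adjusted over the list alone, Ephx1 at -1.03 ± 0.10 and Eda2r at -0.61 ± 0.06 among them, at adjusted p = 0.0142, and adjusted p = 0.114 with an estimated correlation. Cdkn1a did not pass, at -0.04 ± 0.05 (adjusted p = 0.563), and neither did the ribosomal proteins (0.0657, though 0.0463 without replicate 1 of Mettl3 knockdown) nor the stress list (0.461).

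The plot of knockdown effects shows these genes side by side in the 4 comparisons at 0 h, where 1236 genes rose and 1059 fell throughout, against 35.3 in all for independent lists, although the time course knockdowns share their control. Within the repeat set, whose knockdowns have separate controls, the effects correlated across genes at r = 0.78 (rho = 0.695). They shared 1848 higher and 1667 lower genes against 511.7 and 433.6 for independent lists, and in 83 genes the calls were opposite. Between the sets r was 0.662 (rho = 0.582) for Mettl14 and 0.756 (rho = 0.678) for Mettl3 knockdown, with 203 and 94 genes opposite. Mettl14 shared 1677 higher and 1465 lower genes between the sets, against 555.5 and 502.3 for independent lists, and Mettl3 shared 1762 and 1624, against 509.2 and 477.1. The difference between the sets was itself tested, and passed for 2439 genes in Mettl14 knockdown, with the effect higher in the time course for 1162 and lower for 1277. The long-lived scaling moved that split to 731 and 2247. For Mettl3 knockdown it passed for 1450 genes, 909 and 541, and for 951 or 940 without replicate 1 or replicate 2 of its scramble control in the repeat set. Thbs1 and Cysltr1, among the largest rises of the time course, had smaller effects in the repeat set. The effect in the time course minus that in the repeat set was 2.54 ± 0.12 and 3.05 ± 0.22 for Mettl14. For Mettl3 knockdown this difference was 2.15 ± 0.12 and 2.57 ± 0.22.

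**Figure D1:**
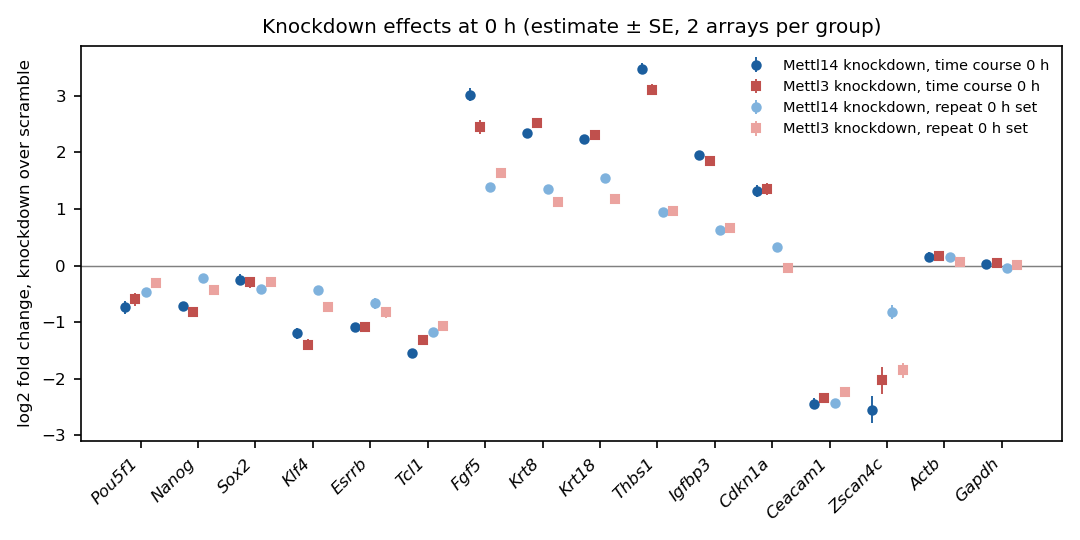
Log2 change against scramble at 0 h (vertical axis) for 16 genes in the 4 knockdown comparisons, with bars for the standard error from limma. Ceacam1 fell in all 4 comparisons, while the values of Thbs1, Igfbp3 and Cdkn1a are higher in the time course than in the repeat set for each knockdown.

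Over 8 h in scramble, 30 of 40 short-lived transcripts and 15 of 17 histones fell, and 25 of 37 long-lived transcripts rose. These calls are against no change in the normalized values. The pluripotency regulators separated: Sox2 at -2.69 ± 0.10, Klf4 at -2.10 ± 0.10 and the growth regulator Myc at -2.08 ± 0.14 fell, whereas Nanog did not pass at 0.03 ± 0.05, or lay at -0.34 when the long-lived list was set equal. The secreted growth factor gene Bmp4 at -3.00 ± 0.13, the feedback inhibitor of growth factor signalling Spry2 at -2.87 ± 0.08 and Cdkn1a at -2.42 ± 0.11 fell too. The largest falls included the histone genes, listed as not polyadenylated, H1f5 at -4.60 ± 0.23 (adjusted p = 1.35e-08) and H2ac1 at -3.36 ± 0.07 and the non-coding Dleu2 at -4.17 ± 0.18. The largest rises included Rps13 at 1.33 ± 0.22, the mitochondrial ND6 at 1.13 ± 0.12, Mrpl47 at 1.12 ± 0.24, Chp1 at 1.10 ± 0.19 and Pcbd1 at 1.08 ± 0.08. In all, 5799 genes rose and 3197 fell, but 14 rose and 774 fell at least 2-fold. The median of all genes was 0.148, and setting the long-lived list equal shifted it by -0.38 to -0.23, so these changes are relative between genes. That scaling gave 579 higher and 7138 lower genes, and quantile normalization again gave 7897 and 2670. The deposited arrays themselves differ with time: the median of probe sets outside the probe table was 5.95 to 6.08 at 0 h, 5.54 to 5.60 at 4 h and 5.52 to 5.60 at 8 h. Actb and Gapdh, at 0.15 ± 0.08 and 0.09 ± 0.04 in scramble, were lower when the long-lived list was set equal, at -0.23 and -0.28.

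By list, 30 of 40 short-lived transcripts fell and 4 rose in scramble over 8 h, also 30 and 4 adjusted over the list alone, with a list median of -0.88 (adjusted p = 6.02e-12). The members that rose, given after their values were seen, were Jun at 0.49 ± 0.09, Ier5 at 0.60 ± 0.12, Fos at 0.49 ± 0.16 and Maff at 0.46 ± 0.14. With the long-lived list equal none of the 4 passed, at 0.11, 0.23, 0.11 and 0.08. Fos lost its call without replicate 1 or 2 of scramble at 0 h (adjusted p = 0.062 and 0.0779) or replicate 2 at 8 h (0.183), and Maff without replicate 2 at 0 h (0.0862) or replicate 1 at 8 h (0.0514). The replication-dependent histones fell in 15 and rose in 1 of 17 cases, with 15 lower adjusted over the list alone and a median of -1.88 (adjusted p = 1.28e-09). Their transcripts are listed as not polyadenylated and the RNA was poly(A)-purified, so these values also depend on how much RNA without a tail was carried over, which was not tested. The probe sets outside the probe table had lower medians at 8 h too, as given above. Targets of p53 fell in 13 of 22, also 13 adjusted over the list alone (adjusted p = 9.79e-05). Long-lived transcripts rose in 25 of 37 cases, or 26 adjusted over the list alone, by a median of 0.25 (adjusted p = 0.000249), Ndufb9 by 0.57 ± 0.05 among them. FGF-ERK feedback genes fell in 10 of 16, also 10 adjusted over the list alone. As a list they passed at adjusted p = 2.14e-05, and adjusted p = 0.0523 with an estimated correlation. Ribosomal protein genes rose in 43 of 59, also 43 adjusted over the list alone, such as Rps29 at 0.79 ± 0.06. The list test gave adjusted p = 0.000215, and adjusted p = 0.0697 with an estimated correlation. Pluripotency genes fell in 18 of 34 and rose in 6. This list passed at adjusted p = 0.000222, and adjusted p = 0.0757 with an estimated correlation. Feeder markers rose in 12 of 23, Col4a1 by 0.92 ± 0.07. By camera it passed at adjusted p = 0.0261, and adjusted p = 0.0757 with an estimated correlation. Primed epiblast genes and the m6A list missed the threshold at adjusted p = 0.0514 and 0.0514, with the adaptor Cbll1 of the m6A complex at -1.70 ± 0.08. Each list passed without replicate 2 of scramble at 0 h (0.0354 and 0.0486) or without some arrays of other groups, through the adjustment (0.0471 to 0.0499).

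Over 8 h in Mettl14 and Mettl3 knockdown, the falls were -2.53 ± 0.10 and -2.66 ± 0.10 for Sox2, -1.93 ± 0.14 and -2.09 ± 0.14 for Myc, and -4.57 ± 0.23 and -4.08 ± 0.23 for the histone gene H1f5. They were -1.08 ± 0.10 and -1.06 ± 0.10 for Klf4, -1.77 ± 0.13 and -1.93 ± 0.13 for Bmp4, and -3.53 ± 0.09 and -3.25 ± 0.09 for Ccn1, a matrix gene of the early response, against -2.10, -3.00 and -1.51 in scramble. Nanog did not pass in either, at 0.07 and -0.03. In Mettl14 knockdown 5449 genes rose and 2866 fell, with 28 and 582 at least 2-fold, and in Mettl3 knockdown 5463 and 2832, with 29 and 547. Setting the long-lived list equal gave 2544 and 4123 in Mettl14 and 1454 and 5804 in Mettl3 knockdown, with shifts of the median gene of -0.17 and -0.27. The 3 treatments shared 3957 higher and 2215 lower genes, and 431 fell at least 2-fold in all 3. Across genes the 8 h changes correlated at r = 0.894 and 0.887 between scramble and the knockdowns and 0.946 between the knockdowns, which share no array. Short-lived transcripts fell in 33 and 34 of 40 cases and rose in 1 and 1, the same numbers adjusted over the list alone (adjusted p = 6.17e-19 and 8.61e-19). The member that rose was Maff, at 0.46 ± 0.14 and 0.49 ± 0.14, or 0.29 and 0.22 without a call when the long-lived list was set equal. It lost its call without replicate 1 of Mettl14 knockdown at 0 h or 8 h (adjusted p = 0.108 and 0.0657), and without replicate 2 at 0 h or replicate 1 at 8 h of Mettl3 knockdown (0.114 and 0.0788). Histones, with the same limit of poly(A)-purified RNA as in scramble, fell in 15 and 15 of 17 (2.06e-11 and 1.5e-10). FGF-ERK feedback genes fell in 12 and 11 of 16 (adjusted p = 7.59e-07 and 2.16e-06), with Spry2 at -2.59 ± 0.08 and -2.67 ± 0.08. Targets of p53 fell in 12 and 10 (0.000624 and 0.00376). Long-lived transcripts rose in 23 and 26 of 37 cases, or 25 and 26 adjusted over the list alone (adjusted p = 0.000487 and 0.000117). Ribosomal proteins rose in 40 and 39 of 59. As a list they passed at adjusted p = 0.000772 and 0.000596, and adjusted p = 0.0774 and 0.0757 with an estimated correlation. Pluripotency genes passed downward at adjusted p = 0.0111 and 0.000512, and adjusted p = 0.189 and 0.0795 with an estimated correlation. Primed epiblast genes did so at adjusted p = 0.0463 and 0.0309, and adjusted p = 0.181 and 0.15 with an estimated correlation. In Mettl14 knockdown they did not pass without its replicate 1 at 0 h (0.0664), nor, through the adjustment, without some arrays of other groups (0.0506 and 0.0522). In Mettl14 knockdown the m6A and cell cycle lists also passed downward, at adjusted p = 0.0392 and 0.0261, and adjusted p = 0.296 and 0.207 with an estimated correlation. The m6A list did not pass without replicate 1 of Mettl14 knockdown at 0 h (0.0664) or at 8 h (0.0822).

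The falls were well under way at 4 h. In scramble Sox2 stood at -1.85 ± 0.10, Spry2 at -2.23 ± 0.08, Bmp4 at -2.19 ± 0.13 and H1f5 at -3.97 ± 0.23 after 4 h, and in the knockdowns Ccn1 stood at -3.35 ± 0.09 and -3.20 ± 0.09. At 4 h 4838 genes rose and 2001 fell in scramble, 4882 and 1944 in Mettl14 knockdown and 4662 and 1930 in Mettl3 knockdown. With the long-lived list equal these were 678 and 3624, 1632 and 3017, and 922 and 3954. Many knockdown effects of 0 h were still present at 8 h: Thbs1 stood 3.08 ± 0.09 and 2.77 ± 0.09 above scramble, Krt8 1.93 ± 0.05 and 2.11 ± 0.05, and Nanog at -0.68 ± 0.05 and -0.88 ± 0.05, for Mettl14 and Mettl3 knockdown. Klf4 no longer passed for Mettl14 at 8 h, at -0.18 ± 0.10, and lay at -0.37 ± 0.10 for Mettl3 knockdown. At 4 h 2958 genes were higher and 2886 lower than scramble in Mettl14 and 2863 and 2727 in Mettl3 knockdown. At 8 h these were 3525 and 2926, and 3519 and 2815, or 5251 and 1396, and 4517 and 1454, with the long-lived list equal. At all 3 times 2133 genes were higher and 1908 lower in Mettl14, and 2079 and 1694 in Mettl3 knockdown.

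The question whether transcripts were lost at a different pace after Mettl14 knockdown was approached by the difference between the 8 h changes of knockdown and scramble, which does not separate loss from synthesis. Among pluripotency genes, those with higher 8 h changes in the knockdown included Tbx3 at 1.06 ± 0.12, Klf4 at 1.02 ± 0.14 (adjusted p = 0.00206), the growth factor gene Fgf4 at 1.00 ± 0.13 and Klf2 at 0.78 ± 0.12. The same held for Bmp4 at 1.23 ± 0.19, the heparan sulfate enzyme gene Hs6st1 at 1.31 ± 0.10, the receptor gene S1pr2 at 1.25 ± 0.11, Cdca4 at 1.18 ± 0.15, Siah1a at 1.17 ± 0.18 and Wtap, a partner of the m6A writer, at 0.62 ± 0.09. Genes with lower 8 h changes included Ccn1 at -2.02 ± 0.13, Jun at -1.52 ± 0.13, Irs2 at -1.29 ± 0.17 and Irf2 at -1.18 ± 0.17. Mettl14 itself was lower at -0.96 ± 0.19 (adjusted p = 0.0139), so the level of its transcript in the knockdown was not constant over the 8 h. Jun, Ccn1 and Irs2 had started higher in the knockdown, and at 8 h Jun stood at -0.02 ± 0.09 against scramble. The difference passed for 738 genes, 530 higher and 208 lower in the knockdown. Of the 530, 425 fell in scramble, and their median 8 h change was -0.611 in scramble and -0.0857 in the knockdown. The median of the 208 was 0.0601 in scramble and -0.436 in the knockdown. Quantile normalization again gave 367 higher and 302 lower genes, and setting the long-lived list equal, which shifted the median gene by 0.20, gave 3192 and 65. The count was 327 without replicate 1 and 369 without replicate 2 of scramble at 0 h, 372 without replicate 2 of scramble at 8 h, and 377 and 469 without replicate 2 of the knockdown at 0 h and at 8 h. On a scale from 0 at scramble 0 h to 1 at scramble 8 h, replicate 2 of Mettl14 knockdown at 0 h stood at 0.088 and replicate 1 of Mettl3 knockdown at 0.093, against -0.007 and 0.007 for scramble. At 8 h the Mettl14 knockdown arrays stood at 0.924 and 0.833 and those of Mettl3 knockdown at 0.848 and 0.897, against 0.954 and 1.046 for scramble. The scramble arrays define this scale, so their means are 0 and 1 by construction. Without the arrays at 0.088 and 0.093 the count was 368, an alternative chosen after seeing the data.

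By list, 10 of 34 pluripotency genes had a higher 8 h change in Mettl14 knockdown than in scramble, or 11 adjusted over the list alone. The list test gave adjusted p = 0.000176, and adjusted p = 0.0756 with an estimated correlation. Pou5f1 at 0.64 ± 0.16 and Esrrb at 0.49 ± 0.12 passed with all arrays (adjusted p = 0.0435 and 0.0342). The adjusted p of Pou5f1 lay at 0.062 to 0.144 without an array compared, other than replicate 2 of Mettl14 knockdown at 0 h, and that of Esrrb at 0.0595 to 0.115 without an array other than replicate 1 of that knockdown at 8 h. Nanp at 1.50 ± 0.33 lost its call without replicate 1 of scramble at 0 h (adjusted p = 0.0969), replicate 2 of scramble at 8 h (0.0766), or replicate 2 of the knockdown at 0 h (0.0936) or 8 h (0.0754). Short-lived transcripts were lower in 9 and higher in 5 of 40 cases, or 14 lower adjusted over the list alone. This list passed at adjusted p = 0.00104, and adjusted p = 0.146 with an estimated correlation. Endoderm and cell cycle lists passed downward with 1 and 3 members called, at adjusted p = 0.00844 and 0.0352, and adjusted p = 0.0981 and 0.221 with an estimated correlation. With the long-lived list equal, the cell cycle list changed direction and did not pass. The endoderm list did not pass without replicate 2 of the knockdown at 0 h (0.0549) or 8 h (0.112), nor the cell cycle list without replicate 1 of scramble at 0 h or 8 h (0.101 for each) or of the knockdown at 0 h (0.0884) or 8 h (0.127).

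In Mettl3 knockdown the 8 h change of Klf4 was higher than in scramble at 1.03 ± 0.14, Bmp4 at 1.08 ± 0.19, S1pr2 at 1.19 ± 0.11, Phospho2 at 1.11 ± 0.09, Fgf4 at 0.90 ± 0.13, Klf2 at 0.82 ± 0.12, Tbx3 at 0.82 ± 0.12, the stress response gene Herpud1 at 0.94 ± 0.09 and Wtap at 0.74 ± 0.09. Ccn1 was lower at -1.74 ± 0.13 (adjusted p = 7.45e-05), Jun at -1.43 ± 0.13, Irs2 at -1.23 ± 0.17 and Irs1 at -1.12 ± 0.19. The probe set shared by Mettl3 and Tox4 was lower too, at -0.75 ± 0.14 (adjusted p = 0.0138), so the targeted transcript was not constant here either. Nanp at 1.82 ± 0.33 lost its call without replicate 1 of scramble at 0 h (adjusted p = 0.051) or replicate 1 of the knockdown at 0 h (0.0523) or 8 h (0.0516). The difference passed for 513 genes, 364 higher and 149 lower. Of the 364, 323 fell in scramble, with medians of -0.764 in scramble and -0.184 in the knockdown. The split was 253 and 215 after quantile normalization again and 722 and 60 with the long-lived list equal, a shift of 0.10. The count was 242 and 282 without replicate 1 or 2 of scramble at 0 h, 258 without replicate 2 of scramble at 8 h, and 262 and 222 without replicate 1 of the knockdown at 0 h or at 8 h. Without the arrays at 0.088 and 0.093 on the scale above it was 262, also chosen after seeing the data. Short-lived transcripts were lower in 8 and higher in 4 of 40 cases, or 13 adjusted over the list alone. By camera it passed at adjusted p = 0.00302, and adjusted p = 0.187 with an estimated correlation. It did not pass without replicate 1 of scramble at 8 h (0.0552). Targets of p53 were higher in 4 of 22, or 9 adjusted over the list alone. As a list they passed at adjusted p = 0.0243, and adjusted p = 0.0771 with an estimated correlation. It did not pass without replicate 2 of scramble at 0 h (0.113). The Hox list, with 1 member called, and the endoderm list, through small changes, passed downward at adjusted p = 0.00208 and 0.0189, and adjusted p = 0.0774 and 0.137 with an estimated correlation. The endoderm list did not pass without replicate 1 of the knockdown at 8 h (0.0618). The pluripotency list lay at adjusted p = 0.0514, and passed without replicate 1 of scramble at 8 h (0.0288) or replicate 1 of the knockdown at 0 h (0.0488). The knockdowns shared 282 higher and 85 lower genes, where independent lists would share 13 and 2.1. The differences correlated across genes at r = 0.783, against 0.5 for simulated unchanged groups that share the scramble arrays, with a covariance of 0.0452 against 0.0112. By 4 h the difference passed for 16 genes in Mettl14 knockdown, 11 higher and 5 lower, and for 9 in Mettl3 knockdown, 2 higher and 7 lower, where 1273 and 1252 genes had an unadjusted p under 0.05. Without any single array compared those counts lay between 4 and 6, and between 3 and 10.

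**Figure D2:**
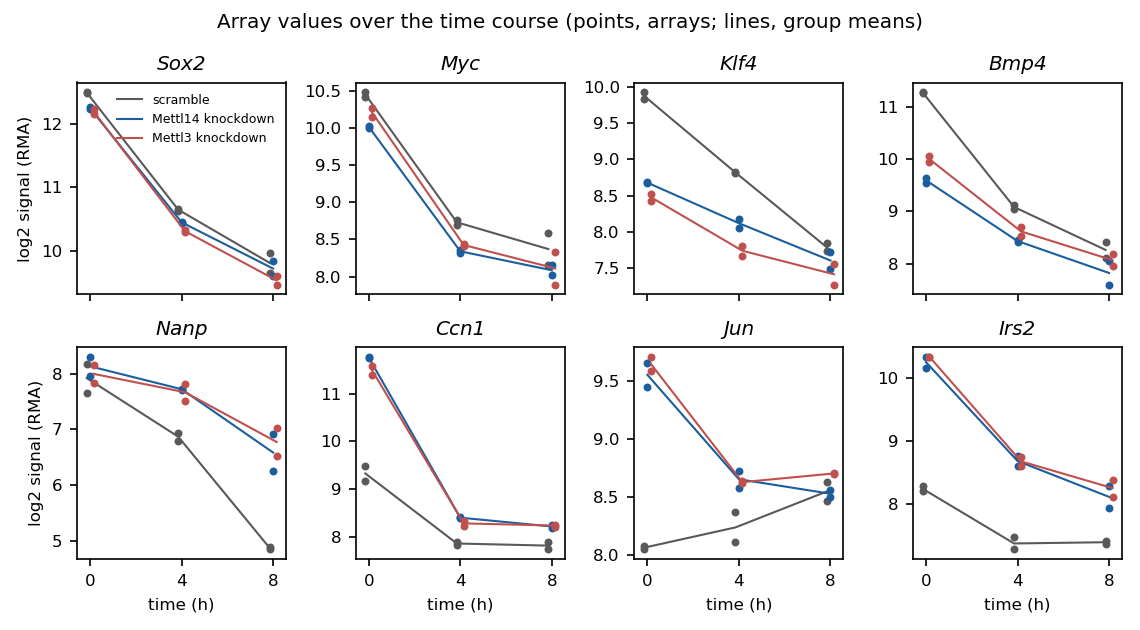
Log2 RMA signal (vertical axis) against time in hours for 8 genes in scramble, Mettl14 knockdown and Mettl3 knockdown, with points for arrays and lines through group means. Klf4, Bmp4 and Nanp had higher and Ccn1, Jun and Irs2 lower 8 h changes in the knockdowns than in scramble, and the change of Sox2 and Myc did not pass the test of a difference.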

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

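The tests of explanations in this part were all chosen after the results were seen.

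The 8 h change differed between knockdown and scramble in 738 genes for Mettl14 and in 513 for Mettl3, and the 4 h change in 16 and 9, by the test of the difference itself. Klf4, Tbx3, Fgf4 and Bmp4 had higher and Ccn1, Jun and Irs2 lower 8 h changes in each knockdown. The knockdown effect at 0 h differed between the time course and the repeat set in 2439 genes for Mettl14 and 1450 for Mettl3, by the same kind of test. Of the regulators named beforehand, the effect in the time course was lower by a difference of -0.50 ± 0.06 for Nanog (adjusted p = 3.16e-05), -0.76 ± 0.13 for Klf4 (0.000486) and -0.41 ± 0.13 for Esrrb (0.0318) in Mettl14 knockdown. In Mettl3 knockdown the differences were -0.38 ± 0.06 for Nanog (0.000612) and -0.66 ± 0.13 for Klf4 (0.0026). It was higher by 1.33 ± 0.09 for Igfbp3 (adjusted p = 9.06e-08) and 0.99 ± 0.14 for Cdkn1a (0.000147) with Mettl14, and by 1.17 ± 0.09 (6.79e-07) and 1.39 ± 0.14 (8.43e-06) with Mettl3. The mean over 22 p53 targets differed by 0.72 and 0.68. The pluripotency list as a whole did not pass in this contrast for Mettl14 knockdown. Of its 34 genes 8 were higher and 11 lower, with a mean of -0.06 (camera adjusted p = 0.873, a test added after seeing the data).

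Targets of p53 such as Plk2, Trp53inp1 and Cdkn1a rose in the time course but not as a list in the repeat set, the contrast between the sets being higher in 19 and 18 of 22 genes (adjusted p = 1.61e-06 for each with an estimated correlation, a list test added after seeing the data). Smaller effects throughout the repeat set are not the whole cause, since the list lay below what the overall slope gives by -0.39 ± 0.07 for Mettl14 and -0.47 ± 0.07 for Mettl3 knockdown. These errors are over the list members and treat genes as independent. A weaker loss of the targeted transcript was not seen for Mettl3, whose probe set, shared with Tox4, fell no less in the repeat set (difference -0.19 ± 0.12). For Mettl14 (0.34 ± 0.16) it cannot be told apart. Protein and m6A were not measured on these arrays, so a knockdown with a weaker effect on them stays open for both. The repeat scramble arrays themselves had p53 targets higher than the time course scramble, relative to all genes, by 0.49 ± 0.10 for the Mettl14 and 0.41 ± 0.09 for the Mettl3 controls, while the knockdown groups differed by -0.22 and -0.26. This cannot be told apart from the set, since each control belongs to a single set. A p53 response to the transfection or culture of the controls in the repeat set may be a candidate explanation, and no biological explanation was tested.

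The 8 h change was higher than in scramble in 530 genes with Mettl14 and 364 with Mettl3 knockdown, Klf4, Bmp4 and S1pr2 among them, of which 425 and 323 fell in scramble. A lower start in the knockdown cannot apply to the 155 and 124 of them called higher at 0 h of the time course, by their selection. It stays open for the 149 and 87 called lower there, Klf4 and Bmp4 among them, of which 77.9% and 89.7% were also lower in the repeat set. Their median difference was 0.49 and 0.52, against 0.51 and 0.53 for the rest. Of the 530 and 364 genes, 51.3% and 46.2% lay below 0 at 0 h of the time course. The knockdown arrays spanned 0.824 and 0.801 of the scramble change between 0 h and 8 h. The scramble arrays define that scale, so their span is fixed, and noise in it lowers the span of any other group. The standard deviation of the 8 h changes across genes was 0.485 and 0.476, against 0.527 in scramble. Such spans would give a difference of 0.11 and 0.15 (0.03 and 0.05 from the 0 h arrays alone). The observed medians were larger, at 0.50 and 0.53. The genes were chosen by that same difference, which raises their observed median. The comparison therefore cannot decide how far a shorter span is the cause in either knockdown. Scaling is not the whole cause, as 344 of the 530 and 226 of the 364 were still called higher after quantile normalization again, but it sets how many genes lie on each side. Slower loss after knockdown stays open beside renewed synthesis. In the knockdown 146 and 76 of the genes rose, but so did 5449 and 5463 of all 14787 genes. As these changes are relative between genes, such rises do not show new synthesis. The short-lived list had lower 8 h changes than in scramble (adjusted p = 0.00104 and 0.00302, and adjusted p = 0.146 and 0.187 with an estimated correlation). Many of its members were called higher at 0 h in each knockdown, in arrays that this difference also uses. The list therefore does not decide on slower loss in general.

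Markers of feeder fibroblasts such as Tagln and Mmp2 rose in both knockdowns of the time course, which RNA of the feeder cells beneath the stem cells could explain. Collagens, among the most abundant fibroblast transcripts, changed by a median of 0.22 ± 0.10 with Mettl14 and 0.23 ± 0.08 with Mettl3 knockdown over 8 genes, and the 15 other members by a median of 0.64 ± 0.26 and 0.50 ± 0.25. The log2 levels of collagens in scramble had a median of 6.61, with 7.31 for Col1a1, 6.72 for Col1a2 and 6.50 for Col3a1. These lie near the lowest mean kept of 6, which is the limit of the filter. The background was not measured, and changes near it are compressed. With Mettl14 knockdown Tagln and Mmp2 rose more than the collagen median, but the errors of the other members are wide. Feeder RNA therefore cannot be told apart from expression of these genes by the stem cells themselves, which was not tested.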

How the results depend on the processing

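The alternatives without the arrays nearest the later times, with crossed blocks, of the list tests with the long-lived list equal, and for the 4 h changes, the contrast between the sets and the genes called in all 4 comparisons were chosen after seeing the data. Of the counts and correlations recomputed, 314 stayed within 1.5 times the count or the spread and 57 moved. Named genes kept direction and call in 10641 reruns, lost the call in 548, gained it in 26 and reversed in 11. List calls stayed in 5274, were lost in 59, gained in 66 and reversed in 1. Counts at 0 h ranged from 4521 to 6397 for Mettl14 and 4497 to 6218 for Mettl3 knockdown in the time course, and at 8 h from 7717 to 10567 in scramble, apart from the fits with an array left out, which gave 4406 to 5108, 4241 to 4690 and 7386 to 8206. The difference of 8 h changes depended on several choices. Against 738 genes for Mettl14, 345 passed without a filter (more dim genes are tested), 430 with array weights, 3257 with the long-lived list equal, 1168 in a fit of all 26 arrays. It was 368 without the arrays nearest the later times and 327 to 766 with an array left out. Against 513 for Mettl3 these were 251 without a filter, 789 with trend and robust, 782 with the long-lived list equal, 972 over all 26 arrays. It was 262 without the arrays nearest the later times and 222 to 633 with an array left out. For the 4 h difference, against 16 for Mettl14, they were 5 without a filter, 36 with a stricter filter, 70 with trend and robust, 10 with the replicate block, 35 with array weights, 44 after quantile normalization and 92 over all 26 arrays. They were 7 without the arrays nearest the later times and 4 to 6 with an array left out. Against 9 for Mettl3 they were 24, 50, 24, 18 and 56 with the stricter filter, trend and robust, array weights, quantile normalization and all 26 arrays. The range with an array left out was 3 to 10. The 4 h change in scramble gave 4302 genes with the long-lived list equal, against 6839, and the contrast between the sets for Mettl3 940 to 1164 with an array left out, against 1450. List tests passed in 33 cases with an estimated correlation, against 70. Correlations of effects without a filter were 0.863 and 0.64 between knockdowns in the time course and the repeat set and 0.56 and 0.635 between sets for Mettl14 and Mettl3. They were 0.846 and 0.847 with the scramble arrays split. With the long-lived list equal, the 8 h change in scramble reversed for Nes (-0.04), Tbx6 (-0.04), Lamb1 (-0.07), Hoxb9 (-0.04), Nanog (-0.34), Actb (-0.23) and Gapdh (-0.28). It did so in Mettl3 knockdown for Igfbp3 (-0.24) and Gapdh (-0.19), as that scaling lowers every 8 h change. It also reversed the cell cycle list in the Mettl14 difference (adjusted p = 0.919). With the mean of a gene's probe sets, Rps28 at 8 h in Mettl14 knockdown reversed to -0.31 and Ythdf1 in Mettl3 knockdown to 0.09. Apart from these stated constructions, the cause was not tested. Same-numbered arrays were not paired: their deviations correlated across genes at -0.436 to 0.122. The values of -0.436 and -0.246 for the 8 h changes in Mettl14 and Mettl3 knockdown mean that opposite-numbered arrays deviated alike. The replicate block gave 5751, 5536, 5113 and 5023 genes for the knockdowns at 0 h, 8939, 8234 and 8228 for the 8 h changes, 662 and 478 for their differences and 71 list tests. Crossed blocks gave 5486 genes for Mettl3 knockdown at 0 h and 8232 and 8304 for the 8 h changes in Mettl14 and Mettl3 knockdown. The differences of 8 h changes were not fitted with crossed blocks. Near the background, changes are compressed, and genes with a mean below 6 were not tested.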

Other observations

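The tests of hypotheses in this part and the list tests between the sets were all chosen after the results were seen.

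Beside the p53 targets, other gene lists differed between the time course and the repeat set in the size of the knockdown effect, adjusted over 40 list tests. Primed epiblast genes had a higher effect of Mettl14 knockdown in the time course by a mean of 0.61 over 13 genes, with 7 called higher (adjusted p = 1.57e-05, and adjusted p = 0.00582 with an estimated correlation). Fgf5 differed by 1.65 ± 0.16 and Pou3f1 by 1.06 ± 0.12. Feeder markers differed by 0.43 with Mettl14 (adjusted p = 0.00017, and adjusted p = 0.00417 with an estimated correlation), Tagln by 1.39 ± 0.10, and by 0.28 with Mettl3 knockdown (adjusted p = 0.0217, and adjusted p = 0.051 with an estimated correlation). The stress list was lower in the time course by -0.17 with Mettl14 and -0.29 with Mettl3 knockdown (adjusted p = 0.0234 and 0.00121 with an estimated correlation), with Chac1 at -1.08 ± 0.14 and -1.29 ± 0.14. Two-cell-like genes were lower by -0.69 with Mettl14 (adjusted p = 0.0157, and adjusted p = 0.193 with an estimated correlation), with Zscan4e at -2.18 ± 0.22. Cell cycle genes were lower by -0.08 with Mettl14, with 7 called lower (adjusted p = 0.0438, and adjusted p = 0.235 with an estimated correlation). Pluripotency genes were lower by -0.16 with Mettl3 knockdown (adjusted p = 0.000698, and adjusted p = 0.0612 with an estimated correlation), and short-lived transcripts higher by 0.19 (adjusted p = 0.00543, and adjusted p = 0.193 with an estimated correlation). The scramble controls of the sets differed too, which was not tested. The repeat scramble minus the time course scramble had a median of 0.64 for two-cell-like genes, 0.52 for feeder markers, 0.23 for p53 targets, 0.37 for the insulin-like growth factor system and -0.26 for cell cycle genes, 0.33 for short-lived transcripts, 0.20 for primed epiblast genes, 0.15 for the stress list and -0.21 for pluripotency genes, against -0.15 for all genes. Probe sets outside the probe table had medians of 5.75 to 5.82 in the repeat set, between the time course at 0 h and at the later times.

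Transcripts known to turn over fast, such as Myc and Spry2, would lead the falls over 8 h if little new RNA were made during the incubation. The median of the short-lived list lay below that of the long-lived list by -1.12 ± 0.15 in scramble, consistent with loss of RNA with little new synthesis in most of them, though the labels do not say what was added. The 10 members that were not lower, among them Jun, Ier5, Fos, Maff, Egr1 and Btg2, had a median level of 6.89 in scramble at 0 h. This lies near the lowest mean kept of 6, which is the limit of the filter and not a measured background. How far the dimmer members could still fall is not known, so as a set they do not decide. Their median change was -0.17 ± 0.09 with the long-lived list equal. Jun at a level of 8.06 and Btg2 at 8.80 lay higher and changed by 0.49 ± 0.09 and 0.09 ± 0.09, or 0.11 and -0.28 with the long-lived list equal. Under that scaling Btg2, Atf3, Egr1 and Gadd45g were called lower (limma adjusted p = 0.000345 to 0.0239), and Jun and the other members were not. New synthesis of some transcripts during the incubation therefore stays open.

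If the knockdown slowed the loss of fast-lost transcripts in general, at unchanged synthesis, those lost fastest in scramble would be higher after knockdown. This was not borne out over all genes in the independent repeat set. There the knockdown effect had a rank correlation across genes of 0.0296 for Mettl14 and 0.0334 for Mettl3 with the scramble 8 h change. The medians were -0.02 and -0.03 in the 10% of genes that fell most. Genes that fell in scramble included pluripotency genes lowered there by Mettl14 knockdown, such as Sox2 and Klf4. The short-lived list, however, rose as a list in that set with each knockdown, as given above. A rise of such transcripts therefore stays open. Slower loss of a subset of transcripts, such as those that carry m6A, is not tested by these values, and m6A was not measured here. The genes with a higher 8 h change in a knockdown lay above 0 in the repeat set in 61.3% ± 2.1 of cases for Mettl14 and 58.5% ± 2.6 for Mettl3, against 49.2% and 50.5% of all other genes and 47.6% and 53% of the genes with a lower 8 h change. Slower loss may have raised part of those transcripts, but the errors treat genes as independent, and synthesis was not told apart from loss. Over all genes the effect and the difference of 8 h changes had rank correlations of -0.00915 and -0.0598.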
